A study of Homo sapiens with 4 samples.

How the data were processed

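RNA from OPM2 cells, an established human multiple myeloma (plasma cell tumour) line, was measured on 4 one-colour expression arrays: 2 of cells given the solvent DMSO (control) and 2 of cells given VS-5584, a small-molecule inhibitor of class I PI3 kinases and of mTOR, each after 24 h. Per the labels' protocols, total RNA was column-purified and turned into biotin-labelled cDNA with a whole-transcript amplification kit. The sample labels give a dose of 123 nM, whereas the series' design text gives 125 nM and places it below the 48-h IC50 of the line. Group and replicate number were taken from the sample titles.

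The deposited table holds 1 intensity per probe set and array for 28869 probe sets. RMA is named in the submitters' processing notes as the authors' method, with no version. RMA usually gives log2 values made equal in distribution across arrays. The deposited intensities are on a linear scale, have a lowest value of 19.8 to 20.01 on each array, and differ in distribution between arrays. The step between RMA and these values is not given in the sources used here. The background correction, the software and any added constant are likewise not given. An added constant would make the fold changes of dim genes too small. Scanner files were not used here, so no probe set could be called above or below background, and the number of arrays limits the precision. The labels give no array or culture batch.

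Intensities were turned into log2 values and were not normalized again. Gene names came from the platform annotation supplied with the table: 19310 probe sets carried 1 gene, 1752 carried several and 7807 carried none listed. Only those with 1 gene were named. Of these, 19279 matched the RefSeq table of assembly GRCh38.p14 by gene ID, from which symbols and gene types were taken, and 31 kept the annotation's symbol. No coordinates are given because no genome build is given in the sources used here. The 685 genes with more than 1 probe set were represented by the one with the highest mean over the 4 arrays. Of 18377 genes, the 40% with the lowest mean over all arrays (below an intensity of 48.9) were left out, and 11026 were tested.

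Treated and control arrays were compared with limma 3.58.1 (R 4.3.3; lmFit and eBayes without trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE given with a log2 difference is that of this model. The 21 gene lists, fixed from textbook knowledge, were tested with limma's camera, which compares a list with the other tested genes. The preset correlation between genes was 0.01, and p-values were adjusted over the 21 lists. Camera was run again with the correlation estimated from each list's residuals, and fry was run as a test that does not refer to other genes. Members of a list were counted past the threshold both over all genes and adjusted over the list alone. The gene list, test and naming choices were made before the data were examined.

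The genes named are, first, the 10 largest increases and 10 largest decreases among genes with an unadjusted p under 0.01 whose groups did not overlap, because fewer than 10 genes passed the threshold. They are, second, the 2 members of each list with the smallest unadjusted p, because no member passed over all genes. A fixed panel of 16 genes (drug targets, plasma cell factors and genes of known importance in this line) was added, of which PIK3CA was not analysed here and 1 other is not reported here. Other genes are named only with the statement that they were chosen after their values were seen.

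The gene and list tests were run on simulated data for 11026 genes with the real mean levels and the fitted prior variance, independent between genes. Of 100 genes changed 4-fold, 100% were called, and of 100 genes changed 2-fold, 88% were called. Of the unchanged genes 3 were called. A list shifted by -0.5 on the log2 scale was called, and 0 unshifted lists were. The simulated groups varied equally, and all these genes were changed at once. In the real data the SD of the log2 difference was 0.25 between treated and 0.17 between control replicates. Correlations estimated within real lists reached 0.91. The simulation therefore checks the code and gives neither the power for these data nor camera's rate of false calls. The alternatives tried were the replicate number as a block, median centring, cyclic loess, other filters on dim genes, an intensity trend in the prior variance, averaging of probe sets, other thresholds, an unmoderated test and leaving out each array. Subtracting 16 from every intensity and counting list members without treated replicate 2 were added after the data were seen. The medians of lists and families under each scaling, the genes over 2-fold on each treated array, and the named genes whose difference moved by over 1.5 times, were also computed then. Figures were drawn with matplotlib 3.10.9.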

Results

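Expression was profiled in 4 cultures of OPM2 myeloma cells, 2 given DMSO and 2 given VS-5584 at 123 nM, harvested at 24 h. The aim was to find genes that differ after 24 h of inhibition of PI3 kinase and mTOR, which relay growth-factor and nutrient signals. No earlier time was measured. The titles call the samples biological replicates without saying how the cultures were separated. Limma's p-values for single genes therefore measure the spread between these samples, with a variance partly shared over genes. Camera's p-values with the preset correlation treat the genes of a list as nearly independent. They do not measure how much a list varies between samples. Median intensities over 28869 probe sets ran from 49.3 on control replicate 1 to 52.5 on treated replicate 2. Treated replicate 2 stood apart. Its upper quartile was 106, against 115 to 118 on the other 3 arrays, and its lower quartile 31.9, against 29.9 to 31.0. Its values were thus squeezed together, with 1.74 log2 units between the quartiles against 1.93 to 1.95. Across probe sets, its log2 values correlated with those of the other arrays at r = 0.980 to 0.985, against 0.993 to 0.996 among the others. Among the 11026 genes tested, the SD of the log2 difference was 0.25 between the treated replicates and 0.17 between the control replicates. Treated replicate 1 was about as close to control replicate 1 (SD 0.165) as the controls were to each other (0.167). It lay further from control replicate 2 (0.198). The median gene differed from the control mean by -0.14 on treated replicate 2 and by -0.0022 on treated replicate 1.

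After VS-5584, cell-cycle genes fell as a group, by more than any other of the 21 gene lists. In the G2/M and mitosis list, all 29 tested genes were lower on both treated arrays than on both controls, with a median log2 difference of -0.52, a 1.44-fold decrease. The list passed camera (adjusted p = 1.2e-18), and gave adjusted p = 0.592 with an estimated correlation, which was 0.86. Fry gave adjusted p = 0.537. Adjusted over the list alone, 27 of its genes fell, and none did over all genes tested. CDK1, the kinase that drives entry into mitosis, stood at a log2 intensity of 8.64 ± 0.27 in control and 7.74 ± 0.23 in treated cells (SD, n = 2 each), a difference of -0.90 ± 0.17 (SE). In the list of G1/S and DNA replication genes, 36 of 38 were lower, with a median of -0.48. This list also passed camera (adjusted p = 2.3e-13, and adjusted p = 0.592 with an estimated correlation, which was 0.73). Fry gave adjusted p = 0.537 here too. Adjusted over the list alone, 20 of its genes fell, against none over all genes. GINS1, part of the replicative helicase, and RRM2, a subunit of ribonucleotide reductase, differed by -0.92 ± 0.16 and -0.77 ± 0.16 (SE). CCND2, a D-type cyclin, differed by -0.41 ± 0.18 (limma adjusted p = 0.469), with -0.15 on treated replicate 1 and -0.68 on treated replicate 2.

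The medians of the G2/M and G1/S lists were -0.34 and -0.23 on treated replicate 1 and -0.75 and -0.73 on treated replicate 2. Without treated replicate 2, all 29 G2/M genes and 30 of 38 G1/S genes remained below both controls, and 19 and 7 genes fell when adjusted over the list alone.

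Among single genes tested, 4 were over 2-fold higher and 6 over 2-fold lower on average, the largest difference being 3.08-fold for SNORD116-6. On treated replicate 1 alone, 3 were over 2-fold higher and 0 over 2-fold lower, the largest being PLAAT4 (2.55-fold), and on treated replicate 2 alone 12 and 83 were. AMPD1, an AMP deaminase, stood at 8.95 ± 0.09 in control and 10.25 ± 0.17 in treated cells (log2, SD, n = 2 each), a 2.46-fold difference. PLAAT4, an acyltransferase of phospholipid metabolism, stood at 6.20 ± 0.0025 and 7.38 ± 0.24, a 2.27-fold difference. RASGRP3, an exchange factor that activates Ras proteins, differed by 1.07 ± 0.17 (log2, SE), and SELENOP, a secreted selenium carrier, by 1.06 ± 0.25, with 0.59 on treated replicate 1 and 1.54 on treated replicate 2. CTSO, a lysosomal cysteine protease, MUC13, a membrane mucin, and KDM5B, a histone H3K4 demethylase, differed by 0.97, 0.92 and 0.88. DKK1, a secreted Wnt antagonist made by myeloma cells, differed by 0.83, and the zinc finger gene ZNF737 and the netrin receptor gene DCC by 0.81 and 0.80.

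Among the lower genes, SLC7A11, the cystine importer that supplies glutathione synthesis, was at 7.68 ± 0.12 in control and 6.44 ± 0.59 in treated cells (SD, n = 2), a log2 difference of -1.24 ± 0.23 (SE). The centromere gene CENPW differed by -1.15, the origin-recognition gene ORC1 by -0.97, the mitotic kinesin genes KIF15 and KIF2C by -0.99 and -0.95, and ERCC6L, a mitotic DNA translocase gene, by -0.95. PELO, a ribosome rescue factor, differed by -1.18 and C18orf54 by -1.002. The small nucleolar RNAs SNORD116-6 and SNORD14E differed by -1.62 ± 0.37 and -1.18 ± 0.26 (SE). Both have close copies in the genome, so their signals are uncertain, and SNORD116-6 already varied between the controls (7.79 ± 0.47, SD).

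**Figure D1:**
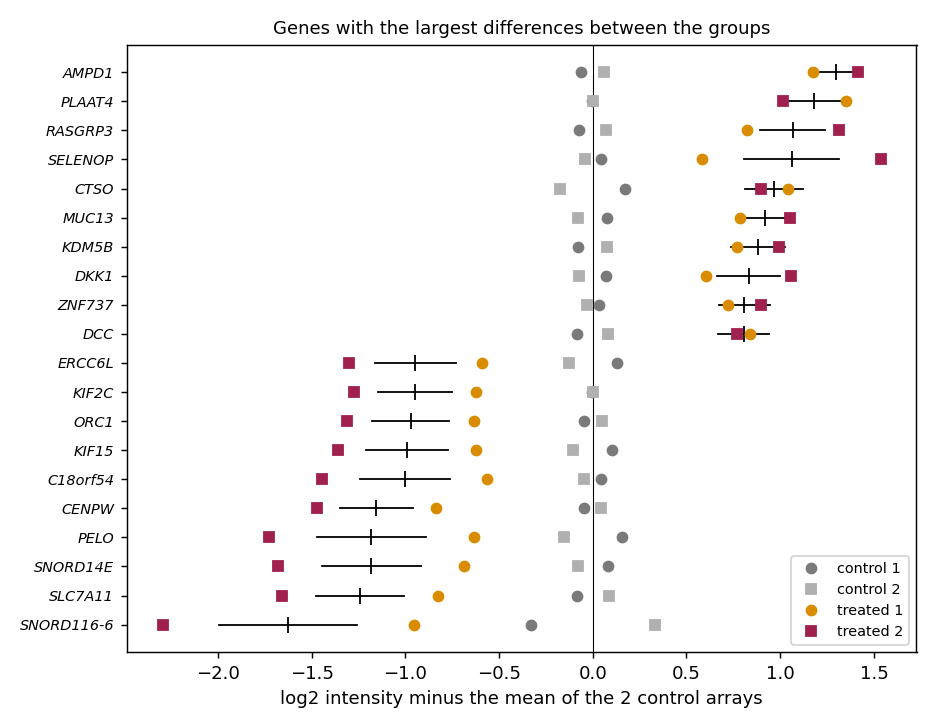
Log2 intensity on each of the 4 arrays relative to the mean of the 2 controls, for the 10 genes with the largest increases and the 10 with the largest decreases; the black tick and line are the mean difference and its SE. All treated points lie outside the control points, by which the genes were chosen, and for the 10 lower genes treated replicate 2 lies further out than treated replicate 1.

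No single gene passed the threshold. With limma, 0 of 11026 genes had an adjusted p under 0.05, the smallest being 0.0640 for AMPD1, while 1149 had an unadjusted p under 0.05, against 551 expected by chance. An ordinary two-sample test also called 0 genes, with 492 at an unadjusted p under 0.05, of which 247 were higher and 245 lower. Of limma's 1149 genes, 164 were higher and 985 lower in treated cells. That split was 482 higher and 877 lower after cyclic loess normalization, and 322 higher and 486 lower without treated replicate 2. The groups did not overlap for 1619 genes that were higher and 3223 that were lower, or 43.9% of genes, where chance gives 33.3%. Chance gives 16.7% in each direction, a share that the lower genes exceeded and the higher genes did not reach. In limma's main fit, too, the excess over chance lay among the lower genes. That asymmetry depended on the scaling and the test. After cyclic loess the 482 higher genes also exceeded their even share of the 551 expected over both directions. The ordinary test showed neither an excess nor a skew. AMPD1 and PLAAT4 each passed in 5 of 8 alternative fits of all 4 arrays, and they were the 2 genes that passed without treated replicate 2. Without treated replicate 2, the log2 differences of 31 of the 73 genes named by the rules shrank by over 1.5 times, 5 grew by over 1.5 times and 5 turned sign. Without treated replicate 1, 2636 genes passed, and without control replicate 1 or 2, 19 and 21 did.

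The proteasome, ribosome biogenesis, aminoacyl-tRNA synthetase and ATF4 lists also fell, by less. The proteasome list had 27 of 28 genes lower and a median of -0.31 (camera adjusted p = 6.4e-07, and adjusted p = 0.592 with an estimated correlation). PSMC6 and PSMB6 differed by -0.46 ± 0.14 and -0.62 ± 0.19 (SE). In the list of ribosome biogenesis and MYC targets, 28 of 29 genes were lower with a median of -0.29 (camera adjusted p = 6.9e-05, and adjusted p = 0.618 with an estimated correlation). POLR1B, a large subunit of RNA polymerase I, differed by -0.49 ± 0.17 and the nucleolar gene NOP16 by -0.50 ± 0.18. MYC itself stood at 9.79 ± 0.27 and 9.80 ± 0.09 (SD, n = 2), a difference of 0.01 whose sign turned negative with median centring. The aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 18 of 19 genes lower and a median of -0.25 (camera adjusted p = 0.0023, and adjusted p = 0.623 with an estimated correlation). MARS1 differed by -0.43 ± 0.18 and HARS1 by -0.41 ± 0.17. The list of ATF4 targets and amino acid supply had 18 of 23 genes lower and a median of -0.32 (camera adjusted p = 0.0023, and adjusted p = 0.592 with an estimated correlation). SLC7A11 was its 1 member that fell when adjusted over the list alone, and PSPH, the last enzyme of serine synthesis, differed by -0.36 ± 0.14.

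No member of these 4 lists passed over all genes, and apart from SLC7A11 none did when adjusted over the list alone. The medians on treated replicates 1 and 2 were -0.18 and -0.42 for the proteasome, -0.12 and -0.42 for ribosome biogenesis, -0.11 and -0.42 for the synthetases and -0.15 and -0.44 for the ATF4 list. After cyclic loess the medians of the last 3 lists were -0.18, -0.16 and -0.21. The synthetase call was lost without treated replicate 2 (camera adjusted p = 0.139, against 2.3e-05 to 0.623 over the alternatives with all 4 arrays).

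Lipid synthesis genes were lower mainly on treated replicate 2, and genes of energy metabolism were lower by small amounts. All 13 fatty acid synthesis genes were lower on average, with a median of -0.36 (camera adjusted p = 0.0034, and adjusted p = 0.618 with an estimated correlation). This median was -0.06 on treated replicate 1 and -0.65 on treated replicate 2. ME1, which makes NADPH for lipid synthesis, differed by -0.50 ± 0.14 (SE), and ELOVL1, a fatty acid elongase, by -0.49 ± 0.19. Of 18 cholesterol synthesis and uptake genes 15 were lower on average, with a median of -0.18, and the list did not pass (camera adjusted p = 0.268). Its medians were 0.11 on treated replicate 1 and -0.48 on treated replicate 2, and ACAT2 and EBP, enzymes of sterol synthesis, differed by -0.47 ± 0.21 and -0.40 ± 0.21. The glycolysis and hypoxia list had 20 of 23 genes lower and a median of -0.21 (camera adjusted p = 0.0394, and adjusted p = 0.718 with an estimated correlation), with GPI at -0.56 ± 0.21 and PKM at -0.41 ± 0.17. Its medians on treated replicates 1 and 2 were -0.06 and -0.32. Oxidative phosphorylation had 28 of 32 genes lower and a median of -0.17 (camera adjusted p = 0.0394, and adjusted p = 0.618 with an estimated correlation), with NDUFA2 at -0.40 ± 0.15 and COX7A2 at -0.30 ± 0.13. Its medians were -0.06 and -0.23. After their medians were seen, these lists were set against 10000 random lists matched on mean level, with genes drawn singly. Oxidative phosphorylation (percentile 2.73) and cholesterol (11.79) lay within the middle 95%, so brightness may account for these average falls. Glycolysis (1.13) and fatty acid synthesis (0.04) lay below it. On treated replicate 2 alone, glycolysis (5.47) and oxidative phosphorylation (15.51) lay within it, and cholesterol (0.05) and fatty acid synthesis (0) below.

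No member of these 4 lists passed over all genes or adjusted over the list alone. The fatty acid call was lost without treated replicate 2 (camera adjusted p = 0.489). The cholesterol list passed as lower without treated replicate 1 (0.0023) or control replicate 2 (0.0017), and as higher without treated replicate 2 (0.0437). The glycolysis call was lost without control replicate 1 (0.0774), control replicate 2 (0.0875) or treated replicate 2 (0.378), and after cyclic loess (0.136), where the median was -0.12. The oxidative phosphorylation call was lost without control replicate 1 (0.0612), control replicate 2 (0.301) or treated replicate 1 (0.137), and kept without treated replicate 2 (0.0381). It was also lost after cyclic loess (0.284), where 23 of 32 genes were lower with a median of -0.071. The cholesterol median was then -0.10. Over the alternatives with all 4 arrays, adjusted p ran from 0.00018 to 0.618 for fatty acid synthesis, 0.0537 to 0.840 for cholesterol, 0.0032 to 0.718 for glycolysis and 0.00010 to 0.618 for oxidative phosphorylation.

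The 4 lists that rose relative to the other genes did so by small amounts. Ribosomal protein genes and other mRNAs with a 5' terminal oligopyrimidine tract, whose translation depends on mTOR, had 33 of 36 members higher and a median of 0.13 (camera adjusted p = 2.0e-07, and adjusted p = 0.592 with an estimated correlation). The medians were 0.12 and 0.14 on the 2 treated arrays. RPL22 differed by 0.37 ± 0.15 and EIF3E by 0.40 ± 0.16 (SE). Many ribosomal protein genes have pseudogenes that can share their signal. In the list of FOXO targets and receptor feedback, 11 of 18 were higher with a median of 0.10 (camera adjusted p = 0.0046, and adjusted p = 0.592 with an estimated correlation). TXNIP, an inhibitor of glucose uptake, rose by 0.60 ± 0.13 when adjusted over the list alone, the 1 member to do so (limma adjusted p over all genes = 0.254). BCL2L11, the pro-apoptotic BH3 protein BIM, differed by 0.43 ± 0.15.

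In the list of BCL2 family and death receptor genes, 11 of 17 were higher with a median of 0.06 (camera adjusted p = 0.0087, and adjusted p = 0.592 with an estimated correlation). BMF, another pro-apoptotic BH3 gene, differed by 0.55 ± 0.16 (SE), and BCL2L11 is also a member. In the list of plasma cell and B cell identity genes, 13 of 20 were higher with a median of 0.10 (camera adjusted p = 0.0054, and adjusted p = 0.592 with an estimated correlation). LY9, a lymphocyte surface receptor, differed by 0.37 ± 0.15 and the chemokine receptor gene CXCR4 by -0.58 ± 0.16. No member of the ribosomal protein, BCL2 or plasma cell lists passed over all genes or adjusted over the list alone. The medians on treated replicates 1 and 2 were 0.15 and 0.03 for FOXO targets, 0.09 and 0.03 for the BCL2 family and 0.17 and 0.03 for plasma cell genes. Control replicate 1 differed from control replicate 2 by medians of -0.01, -0.06 and 0.04 in these lists, in the same order. After cyclic loess these 3 lists had medians of 0.20, 0.15 and 0.18, with 15 of 18 FOXO genes higher. The FOXO call was lost without treated replicate 1 (0.0783), and the BCL2 call without control replicate 1 (0.146) or with no filter on dim genes (0.0817). Over the alternatives with all 4 arrays, adjusted p ran from 0.00017 to 0.592 for FOXO targets and 0.0029 to 0.592 for the BCL2 family.

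**Figure D2:**
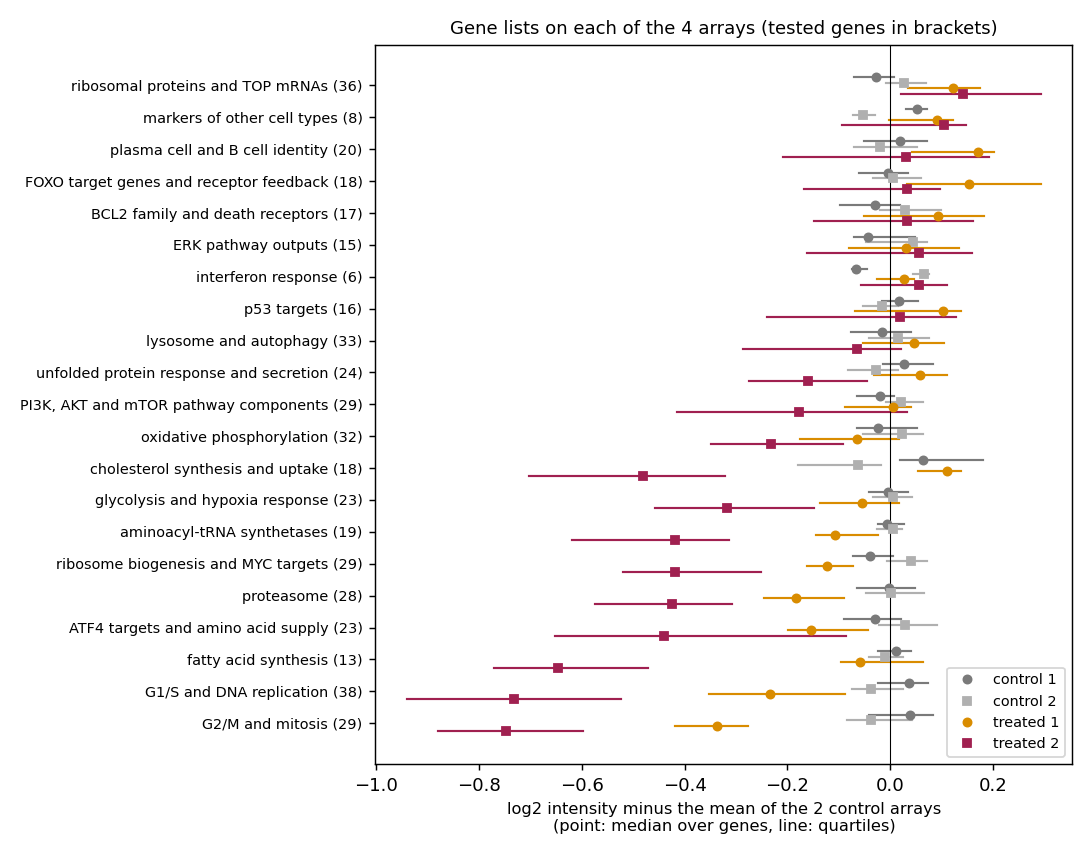
Log2 intensity of the tested genes of each of the 21 lists relative to the mean of the 2 control arrays, for each of the 4 arrays; points are medians over genes and lines run between the quartiles. The G2/M and G1/S medians are at -0.34 and -0.23 on treated replicate 1 and below -0.7 on treated replicate 2, while cholesterol and fatty acid synthesis genes are at 0.11 and -0.06 on treated replicate 1 and at -0.48 and -0.65 on treated replicate 2.

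The PI3K, AKT and mTOR pathway components had 21 of 29 genes lower and a median of -0.09, and did not pass camera (adjusted p = 0.448). Of all tested genes, 6917 of 11026 were lower. The list's medians were 0.0053 on treated replicate 1 and -0.18 on treated replicate 2, and after cyclic loess its median was -0.045 with 17 of 29 lower. PIM2, a survival kinase of myeloma cells, differed by 0.62 ± 0.14 (SE) and RPS6KB1, the S6 kinase downstream of mTOR, by -0.45 ± 0.14. Lysosome and autophagy genes had a median of -0.01 (camera adjusted p = 0.583), with GLA at -0.61 ± 0.17 and GUSB at -0.34 ± 0.16. Genes of the unfolded protein response and secretion had a median of -0.06 (0.557), with SEL1L at 0.22 ± 0.14 and HERPUD1 at -0.21 ± 0.14. For these last 2 lists camera's direction was up, opposite to their medians and means, and after cyclic loess the medians were 0.09 and 0.04. On treated replicates 1 and 2 they were 0.05 and -0.07 for lysosome genes and 0.06 and -0.16 for the unfolded protein response. The list of ERK pathway outputs had a median of 0.05 (0.157), with ETV5 at -0.42 ± 0.15 and PHLDA1 at 0.34 ± 0.13. The p53 targets had a median of 0.04 and a mean of -0.02 (camera up, 0.207), with DDB2 at -0.42 ± 0.16 and TP53INP1 at 0.37 ± 0.14. Of the 25 interferon response genes measured, 6 were bright enough to be tested, with a median of 0.05 (0.263), OAS1 at 0.18 ± 0.14 and BST2 at -0.14 ± 0.14. The medians on treated replicates 1 and 2 were 0.03 and 0.06 for ERK outputs, 0.10 and 0.02 for p53 targets and 0.03 and 0.06 for interferon genes. They were 0.08, 0.09 and 0.01 after cyclic loess, and 0.03, 0.02 and 0.02 with median centring. No member of these lists passed over all genes or adjusted over the list alone.

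Markers of cell types other than plasma cells were mostly among the dim genes, 20 of 28 being left out. The 8 tested had a median of 0.10 and did not pass (camera adjusted p = 0.0737, with none past adjusted over the list alone). The list passed with no filter on dim genes (0.0192), with averaged probe sets (0.0289) and without control replicate 1 (0.04999), against a highest value of 0.592 over the alternatives with all 4 arrays. KRT18, an epithelial keratin, was at 0.49 ± 0.30 (SE), with 1.04 on treated replicate 2 and -0.058 on treated replicate 1, and the endothelial gene PECAM1 was at -0.28 ± 0.19, with -0.57 on treated replicate 2 and 0.0056 on treated replicate 1.

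Transcripts of the drug's targets and of plasma cell factors did not pass. PIK3CB differed by -0.39 ± 0.18 (SE), PIK3CD by 0.08 ± 0.13 and MTOR by -0.28 ± 0.17. On treated replicates 1 and 2, PIK3CB was at -0.11 and -0.66 and MTOR at -0.043 and -0.52. PIK3CG and IRS2, an insulin receptor substrate, were left out as dim, with log2 means of 5.24 and 5.38 in control and 5.21 and 5.40 in treated cells. IRF4, PRDM1 and XBP1, transcription factors of plasma cells, stood at 10.90, 11.10 and 10.50 in control cells and differed by -0.01 ± 0.16, 0.10 ± 0.13 and 0.13 ± 0.13. SDC1, the plasma cell surface marker CD138, differed by -0.14 ± 0.14. FGFR3 and NSD2, genes next to the breakpoint of a recurrent myeloma translocation, differed by 0.17 ± 0.15 and -0.06 ± 0.15. DEPTOR, an inhibitor of mTOR that many myelomas express highly, differed by 0.16 ± 0.14. On treated replicates 1 and 2, IRF4 was at 0.18 and -0.21, PRDM1 at 0.17 and 0.02, SDC1 at -0.05 and -0.22, FGFR3 at 0.28 and 0.06, NSD2 at 0.10 and -0.22 and DEPTOR at 0.28 and 0.03. After cyclic loess IRF4 and NSD2 were positive (0.05 and 0.08), SDC1 was at -0.01 and MTOR at -0.14, and PRDM1, XBP1, FGFR3 and DEPTOR were at 0.15, 0.20, 0.31 and 0.29.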

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

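The subtraction of 16 from every intensity was chosen after the data were seen. The count of genes past the threshold (0 as reported) depended on the fit and the array set. It was 432 with the replicate block (47 higher, 385 lower), 80 with an intensity trend in the prior variance (21 and 59), 58 when the dimmest 60% of genes were left out (13 and 45), 16 after cyclic loess (11 and 5), 2 after subtracting 16 from every intensity (both higher), and 1 at an adjusted p under 0.10. It stayed at 0 with median centring, no filter, averaged probe sets, a minimum fold and the ordinary test. Leaving out 1 array, so that the lone sample is assumed to vary like the other group, gave 2 to 2636 genes, the lowest without treated replicate 2 and the highest without treated replicate 1. All 16 genes of the loess fit, all 58 of the stricter filter and 76 of 80 of the intensity trend were among the 432 of the block. The loess fit shared 11 of its 16 with the stricter filter and 14 with the trend, and the filter 46 of its 58 with the trend. Same-numbered arrays deviated together only weakly (r = 0.16 across tested genes), and 2 shared numbers do not establish a pairing. Of the 3 splits of the 4 arrays into pairs, the real one gave 1149 genes at an unadjusted p under 0.05 and the others 304 and 37; 3 splits cannot give a share under 0.05. The causes were not tested.

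Of the 21 lists, 13 passed camera, 11 to 14 did under the processing alternatives, and 11 to 12 when 1 array was left out. None (0) passed with an estimated correlation (adjusted p of 0.592 for the FOXO, ATF4, G1/S, G2/M, ribosomal protein, BCL2, plasma cell and proteasome lists, 0.618 for fatty acid synthesis, ribosome biogenesis and oxidative phosphorylation, 0.623 for the synthetases, 0.718 for glycolysis), and 0 with fry, where all 13 had 0.537. With 2 residual degrees of freedom the estimated correlations were up to 0.91 (synthetases). Glycolysis lost its call with the replicate block (0.0537), cyclic loess (0.136), the stricter filter (0.253) and the subtraction (0.0548). Oxidative phosphorylation lost it under the same settings (0.0967, 0.284, 0.456 and 0.0723), and the BCL2 family with no filter (0.0817). Markers of other cell types gained a call with no filter (0.0192) and with averaged probe sets (0.0289). The replicate block changed no other list call. Uncalled lists turned direction: lysosome with no filter (0.873) and fry (0.767), unfolded protein response with no filter (0.718) and fry (0.772), and PI3K components with the stricter filter (0.986). Too few interferon and marker genes (under 5) were left to test under the stricter filter.

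When 1 array was left out, adjusted p ran from 0.00047 to 0.0783 for FOXO targets, 0.0017 to 0.650 for cholesterol, 3.4e-05 to 0.489 for fatty acid synthesis, 0.0171 to 0.378 for glycolysis, 0.00027 to 0.139 for the synthetases, 0.279 to 0.992 for lysosome, 0.0017 to 0.146 for the BCL2 family, 0.159 to 0.989 for the unfolded protein response, 0.0381 to 0.301 for oxidative phosphorylation, 0.377 to 0.976 for PI3K components and 0.04999 to 0.197 for other cell types. The other 10 lists kept their call or lack of it and their direction.

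Among single genes, signs turned for MYC, IRF4, NSD2, IRS2, PIK3CG, KRT18 and PECAM1. MYC was -0.0068 with median centring and -0.18 to 0.21 with 1 array left out, IRF4 0.052 after loess and -0.21 to 0.18, NSD2 0.083 and -0.22 to 0.10, and IRS2 -0.031 and -0.070 to 0.11. With 1 array left out PIK3CG ran from -0.12 to 0.064, KRT18 from -0.058 to 1.04 and PECAM1 from -0.57 to 0.0056. The causes were not tested.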

Other observations

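The gene families below, the members named and all tests in this part, except that of the host transcripts of small nucleolar RNAs, were chosen after the results they bear on were seen. The symbol rules of 5 families were corrected after their values were seen, to leave out pseudogenes, an antisense transcript and unrelated genes with like symbols, which gave those families smaller p-values. Of 25 families defined by gene symbol or gene type, several were lower in treated cells. All 20 nucleoporin genes tested, which build the nuclear pore, were lower on average, with a median log2 difference of -0.43 (camera adjusted p over the families = 4.3e-08). NUP35 differed by -0.64 ± 0.17 (SE) and NUP93 by -0.54 ± 0.18. Genes of the Fanconi, RAD and BRCA DNA repair families were lower for 14 of 16 members with a median of -0.35 (0.00046), with RAD51AP1 at -0.61 ± 0.16. Mitochondrial ribosomal protein genes were lower for 65 of 73 members with a median of -0.23 (2.3e-05). Histone genes were lower for 36 of 41 members with medians of -0.27 and -0.31 on the 2 treated arrays (5.8e-08), with H1-5 at -0.805 ± 0.21 and H1-2 at -0.61 ± 0.15, while control replicate 1 already differed from control replicate 2 in these genes by a median of -0.20. No member of these families passed over all genes tested, and with an estimated correlation the families gave adjusted p = 0.587, 0.642, 0.642 and 0.536, in the order named. On treated replicates 1 and 2 the medians were -0.22 and -0.59 for nucleoporins, -0.18 and -0.56 for the repair families and -0.12 and -0.31 for mitochondrial ribosomal proteins. After cyclic loess their medians were -0.28, -0.26, -0.11 and -0.23, with 52 of 73 mitochondrial ribosomal protein genes lower.

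Olfactory receptor genes and 3 kinds of non-coding transcript were higher on treated replicate 2. Olfactory receptor genes had a median of 0.022 on treated replicate 1 and 0.24 on treated replicate 2 (18 of 20 higher on average), microRNA genes 0.05 and 0.25, pseudogenes -0.0062 and 0.11, and long non-coding RNAs 0.04 and 0.11. Camera gave adjusted p over the families of 8.0e-07, 8.0e-07, 6.0e-08 and 5.8e-08, and with an estimated correlation adjusted p = 0.547, 0.536, 0.536 and 0.536. The medians on treated replicate 2 were 0.20, 0.24, 0.15 and 0.10 after cyclic loess. The filter on dim genes used a mean that includes treated replicate 2, the array with the narrower range. These families were not compared with genes matched on brightness, so the rise cannot be told apart from that array's narrower range. None of 3252 other probe sets of sufficient brightness, with no or several listed genes, passed the threshold with limma (0), and 72 had an unadjusted p under 0.05.

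Treated replicate 2 lay further from the controls than treated replicate 1 in the lists that fell. A distortion of that array that depends on brightness alone was set against 10000 random lists matched on mean level. The gap between the treated arrays lay below the middle 95% of matched lists for G2/M (percentile 0.05), G1/S (0), ribosome biogenesis (0.47) and the synthetases (0.33). The same held for cholesterol and fatty acid synthesis together (0). Brightness alone rarely gave such gaps in lists drawn at random. These lists were examined because their gap had been seen, however, and the random genes were drawn singly. Genes that move together could give a wider range, so the distortion is not excluded. The gap lay within the middle 95% of matched lists for the proteasome (3.07), glycolysis (25.34), ATF4 (33.09) and oxidative phosphorylation (55.36), where brightness may account for it. On treated replicate 1 alone, the medians of G2/M, G1/S, ATF4 and proteasome genes were at percentile 0 and that of ribosome biogenesis at 0.34. A larger change of the same genes in the second culture thus stays possible for these lists. Their low medians had been seen beforehand and do not measure how much more that culture changed. A larger change in the second culture also stays open for the synthetases (3.72), glycolysis (15.14), oxidative phosphorylation (15.9) and the fatty acid genes (15.8). The cholesterol genes as a group were not lower on treated replicate 1 (median 0.11, percentile 99.91), nor were the lipid genes together (99.1). These medians too had been seen beforehand, and the random genes were drawn singly, so the comparison does not decide the question. What set the lipid genes apart there, including a difference in culture or in dose received, stays open and was not tested.

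Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, were lower for 69 of 83 members with a median of -0.20, or -0.12 and -0.23 on treated replicates 1 and 2 (camera adjusted p over the families = 0.00012, and adjusted p = 0.536 with an estimated correlation). SNORA33 differed by -0.73 ± 0.13 (SE) and SNORA62 by -0.80 ± 0.14. Control replicate 1 already differed from control replicate 2 in this family by a median of -0.08. For the 44 of these RNAs inside a tested gene, lower RNA levels of that gene are argued against as the whole cause. The 34 tested genes that contain them by position, on either strand, had a median of 0.03 (0.02518, 95% bootstrap interval -0.11 to 0.12). Those 44 RNAs had a median of -0.19. The interval comes from resampling genes, so it does not cover the variation between cultures. The genes that contain SNORA33 and SNORA62 were not tested. Many of the 34 are ribosomal protein genes, whose pseudogenes can share their signal. Transcription was not measured apart from RNA level, so lower transcription of these genes stays open. Poorer recovery of small RNAs in the treated preparations could give the same picture. It stays open, because the 6 Cajal body RNAs bright enough to compare gave a wide bootstrap interval over genes. Their median was -0.127 (interval -0.37 to 0.41). The 26 tested microRNA genes were not used in this comparison. Of these, 21 were higher, with medians of 0.05 and 0.25 on treated replicates 1 and 2. A response of these RNAs to the drug was not tested separately from these explanations.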
